A study of Mus musculus with 2 samples.

How the data were processed

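Dorsal skin of wild-type C57BL/6 mice, described as female, was dissociated with collagenase D and DNase, depleted of dead cells and profiled by droplet-based 3' single-cell RNA sequencing, per the labels' protocols. There was 1 library from untreated skin and 1 from skin given topical imiquimod daily for 5 days, and the labels put each in its group. The values used were raw UMI counts per gene and barcode, as deposited by the authors, with gene lists and barcode lists in matching order. Per the file headers the count matrices were written by Cell Ranger 5.0.0, whereas per the submitters' processing notes Cell Ranger 3.0.2, Seurat 2.0 and the mm10 build were used; the aligner settings and the annotation behind the counts were not given in the sources used here. The listed barcodes all had at least 500 UMIs, which sets a lower limit on the cells that could be seen. Gene positions were taken from GENCODE M21 on GRCm38 by gene ID, which matched 27645 of 27998 IDs.

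Cells with at least 200 genes detected and at most 10% mitochondrial UMIs were kept, and doublets were removed in each library with Scrublet as implemented in scanpy, at an expected rate of 0.8% per 1000 cells. In the control library 192 barcodes had too few genes and 397 too many mitochondrial UMIs, 10297 passed, and 422 (4.10%) were removed as doublets, against 8.24% expected. In the IMQ library the numbers were 558, 552, 8499 and 110 (1.29%), against 6.80% expected, so doublets may remain. The cells kept held 114688094 UMIs in the control and 138302539 UMIs in the IMQ library, with a median of 2636 and 3285 genes. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled with a clip at 10, and 30 principal components and 15 neighbours were used for Leiden clustering of both libraries together at a resolution of 1, with no integration across libraries. A cluster was named after a cell type when at least 3 of its markers were detected (in at least 10% of its cells and at 2 times the level elsewhere) and its 10 leading genes did not favour another type. Markers of 20 cell types and 6 fibroblast subtypes were used, 8 of 284 of which were not found under their symbol in the count files. All 37 clusters were named. Fibroblast-like cells were clustered again at a resolution of 0.5, and subclusters with at least 50 cells of each library were treated as shared.

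For each class the UMIs of each library were summed and divided by their total to give CPM. CPM have exact Poisson intervals, shares of cells have exact Clopper-Pearson intervals, and ratios have exact conditional binomial intervals, all at 95%, and they cover counting error only. Since each group had 1 library, no test, p-value or number of differing genes is given. A gene counted as measured with at least 20 UMIs over both libraries, and as higher or lower when its ratio was at least 2-fold and its interval excluded equality. A ratio against a count of 0 was computed against a floor of 3 counts and is given as a lower bound, and such members enter list medians at their bound. The median of each of 29 gene lists with at least 3 measured members was compared with 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. Of 629 list members, 16 were not found under their symbol. Lists share genes with the cell type markers or with each other, for example 15 of 33 collagen and matrix genes and 9 of 31 differentiation genes are markers, and 17 of 28 IL-17 and NF-kB genes and 20 of 35 inflammatory macrophage genes are in another list.

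Genes were named by a rule that took those with at least 100 UMIs, at least 50 CPM in the higher library, a log2 ratio of at least 1 in size and a level at least 3 times what free RNA could give. Mitochondrial, ribosomal protein and haemoglobin genes were left out. Ranked by the interval bound nearer to equality, the 12 highest and 12 lowest genes were named in fibroblast-like cells and the 6 highest and 6 lowest in other classes, together with 18 fibroblast genes fixed in advance and up to 4 members with the most extreme ratios of each list. Outside this rule Col3a1, Mki67, Cxcl2, Krt1, Krt16, Lor, Il13, C1qa, Icam1 and Vcam1 in single classes, and the genes given for neutrophil-like cells and for cellular sources, were chosen after their values were seen. Markers, gene lists, the naming rule, the minimum of 100 cells per library and most alternatives were fixed before the data were examined. After the data had been seen, classes with at least 30 cells in each library were added, which brought in the macrophage/monocyte-like, endothelial-like and lymphatic endothelial-like classes, and so was the restriction to shared subclusters. A few genes that the rule names are not reported here. Neutrophil-like cells were left out of gene comparisons because the control library held 8 of them. Free RNA was estimated per class and library as the median, over markers of other classes, of their CPM in the class relative to the whole library. The level that free RNA would give for each gene and its subtraction from lists not planned for a class were added after the data had been seen. So were the tracing of cells that changed class under another clustering and keratinocyte-like values without cluster 26 or without cells that held Cd207. Also added were values without the cell that held most UMIs of a gene in each library, as counting intervals do not cover the spread between cells, and the interferon list by pericyte cluster.

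The alternatives were at least 500 genes per cell, at most 5% or 20% mitochondrial UMIs, no doublet removal, resolutions of 0.5 and 2, each library clustered on its own, list genes left out of the variable genes, size factors, CPM without the 50 most abundant genes, the mean over cells, subtraction of free RNA, members with at least 100 UMIs, no minimum with a pseudocount of 1 CPM, and a pseudocount of 5 CPM. The procedure was tested on simulated counts with 200 genes altered by 2.5-fold or 4-fold. In fibroblast-like cells (14642 genes) 91.9% and 100% of them were recovered, with 0.298% of unaltered genes called; in T cell-like cells (8613 genes) 78.1% and 97.6%, with 1.27% called; and in macrophage/monocyte-like cells (8000 genes) 65.3% and 97.6%, with 1.63% called. The simulated counts were Poisson draws from the pooled profile of each class, at the UMI totals of each library. They held no spread between cells or animals, no difference in clusters and no free RNA, so these rates cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9 were used.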

Results

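Single-cell transcriptomes were compared between dorsal skin of untreated C57BL/6 mice aged 2 months and dorsal skin treated daily for 5 days with topical imiquimod (IMQ), a Toll-like receptor agonist that induces a psoriasis-like dermatitis. The series concerns the part that dermal adipocyte formation plays in neutrophilic skin inflammation, so fibroblast-like cells, which include adipocyte precursors, were the first class compared. Each condition was represented by 1 library, and the number of animals behind each library was not given in the sources used here. The control library held 10857 barcodes and 123088680 UMIs, and the IMQ library held 9414 barcodes and 144054978 UMIs. After filtering, 9875 control cells and 8389 IMQ cells were kept, with a median of 9468 and 12543 UMIs per cell. Because there were no replicates, no test of the treatment was possible, and every difference below is a difference between these 2 libraries. Intervals in parentheses are exact 95% intervals that cover counting error only.

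Several leukocyte classes took larger shares of the IMQ library. Neutrophil-like cells made up 0.0810% of control cells and 3.43% of IMQ cells, a 42.4-fold (21.2 to 99.1) higher share that rested on 8 control and 288 IMQ cells. Macrophage/monocyte-like cells, the phagocytes of the dermis, accounted for 0.780% (0.616 to 0.974) of control cells and 6.00% (5.50 to 6.53) of IMQ cells, which was 7.69-fold (6.04 to 9.91) higher in the IMQ library. Basophil-like cells were 8.50-fold (4.21 to 19.4) more frequent in the IMQ library, with 9 control and 65 IMQ cells, and T cell-like cells were 1.53-fold (1.32 to 1.78) more frequent, at 3.13% and 4.79%. Fibroblast-like cells formed 69.4% (68.5 to 70.3) of control cells and 44.9% (43.9 to 46.0) of IMQ cells, a 1.54-fold (1.48 to 1.61) lower share in the IMQ library. Keratinocyte-like cells formed 16.4% (15.6 to 17.1) of control cells and 25.5% (24.5 to 26.4) of IMQ cells, a 1.56-fold (1.46 to 1.66) higher share.

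Both endothelial classes also took larger shares of the IMQ library. The endothelial-like share was 3.83-fold (2.66 to 5.64) higher, with 39 control and 127 IMQ cells, and the lymphatic endothelial-like share 3.96-fold (2.89 to 5.51) higher, with 52 and 175 cells. Red blood cell-like barcodes numbered 16 in the control library and 106 in the IMQ library, and 48 and 107 with list genes left out of the variable genes. Pericyte/smooth muscle-like cells stood at 3.31% and 2.62%, Schwann-like cells at 1.67% and 2.15%, and dendritic-like cells at 1.23% and 1.67%. The counting interval of the ratio included equal shares for natural killer-like cells (1.29% and 1.35%), mast cell-like cells (35 and 32 cells), melanocyte-like cells (41 and 41 cells) and muscle-like cells (78 and 90 cells). With each library clustered on its own, natural killer-like cells were 1.09% and 0.489%, with 72 IMQ cells of the class then T cell-like, and with at least 500 genes detected melanocyte-like cells were 0.433% and 1.65%. All shares depend on the enzymatic digestion, the removal of dead cells, the minimum of 500 UMIs among the listed barcodes and the deeper IMQ library, whose endothelial-like cells had a median of 15859 UMIs against 6261 in the control library. With each library clustered on its own, the log2 ratio of the macrophage/monocyte-like share was 1.51 in place of 2.94. The class then held 214 control cells, of which 120 were otherwise dendritic-like, 9 basophil-like and 8 neutrophil-like. At a Leiden resolution of 0.5 it was 1.93, with 198 control cells.

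**Figure D1:**
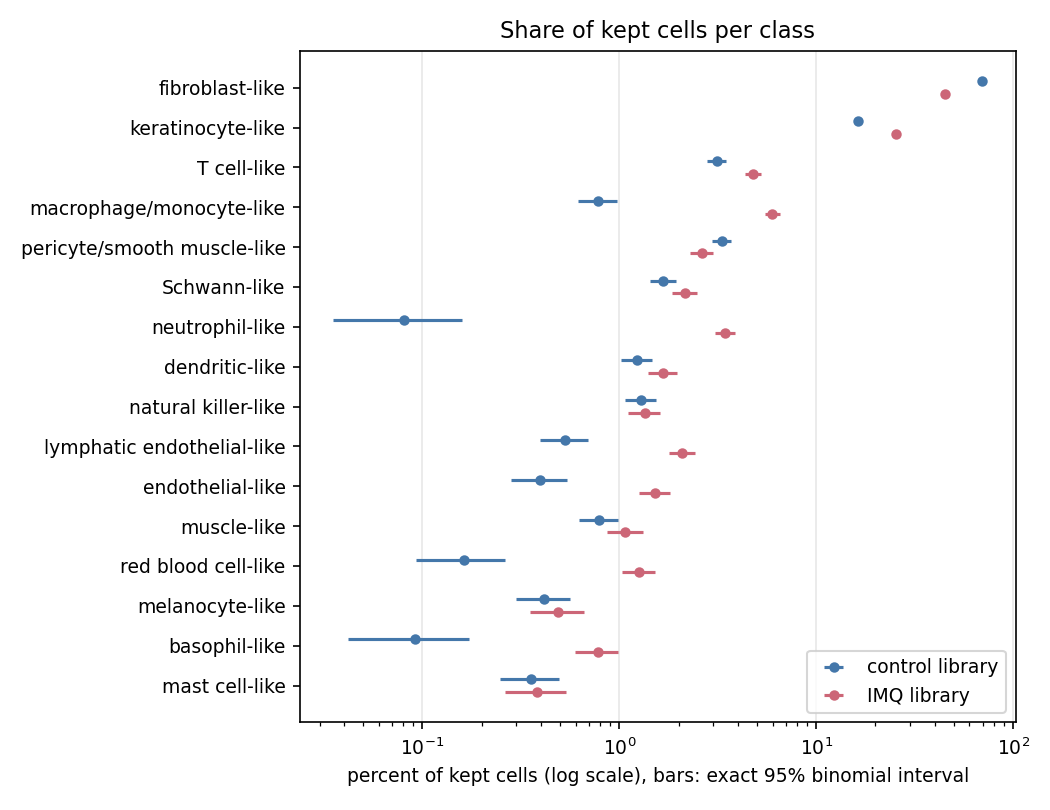
Share of kept cells per class in the control and IMQ libraries, in percent on a log axis, with exact 95% binomial intervals as bars. Neutrophil-like cells lie at 0.0810% and 3.43%, macrophage/monocyte-like cells at 0.780% and 6.00%, and fibroblast-like cells at 69.4% and 44.9%.

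Acute-phase and antimicrobial transcripts were far higher in fibroblast-like cells of the IMQ library. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), a serum amyloid A protein of the acute-phase response, stood at 13.3 CPM in the control library and 9736 CPM in the IMQ library, 733-fold (688 to 782) higher. Lcn2, which encodes the siderophore-binding protein lipocalin, had 8.77 against 877 CPM, and Hp, which encodes haptoglobin, was 66.9-fold (61.0 to 73.4) higher. Saa1 had 0.113 against 95.6 CPM in the control and IMQ libraries, Saa2 was 127-fold (87.3 to 191) higher, and Prg4, which encodes the joint lubricant lubricin, had 7.55 against 907 CPM. Of 18 measured antimicrobial and acute-phase genes, 15 were higher by at least 2-fold, 0 were lower and 3 were neither, with a median log2 ratio of 3.37, above all 10000 random lists matched on expression. Camp, which encodes the cathelicidin antimicrobial peptide, was low in both libraries, at 0.607 (0.439 to 0.818) and 2.25 (1.86 to 2.68) CPM, and its log2 ratio was 0.15 in the shared subclusters. Subtraction of free RNA, estimated at 4.52% of control and 2.72% of IMQ UMIs of the class, gave a median of 2.15 for the antimicrobial list. The median log2 ratio over all 14642 measured genes of the class was 0.27 and size factors shifted it by -0.27, so list medians are also given relative to it; the 50 most abundant genes took 34.5% of control and 25.5% of IMQ UMIs.

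Chemoattractant genes formed the next group. Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), a chemokine that binds CXCR4, was 15.2-fold (14.9 to 15.6) higher, at 107 CPM in the control library and 1631 CPM in the IMQ library, and Cxcl14 was 11.9-fold (11.5 to 12.2) higher. Among the neutrophil chemoattractants and growth factors, 5 of 9 measured genes were higher and 0 were lower, with a median log2 ratio of 1.52 that lay above all 10000 random lists. The most abundant of them, Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), a ligand of the neutrophil receptor CXCR2, stood at 909.7 CPM in the control library and 1502 CPM in the IMQ library, a 1.65-fold (1.63 to 1.67) ratio below the 2-fold rule. Cxcl2, another ligand of this receptor, had 151 against 237 CPM, and Il6 had 182 against 338 CPM. Csf3, the growth factor of the neutrophil lineage, was 71.6-fold (49.7 to 107) higher from a low base of 0.409 CPM and Cxcl5 was 54.8-fold (31.1 to 107) higher. Il1b, at 0.353 and 4.77 CPM, lay below the 1.07 and 7.42 CPM that free RNA would give. Cxcl3, with 3 and 74 UMIs, was below 3 times its own free RNA level in the IMQ library, and both genes are among the 5. With free RNA subtracted, the median of this list was 0.92. Without the highest cell of each library for each gene it was 0.94. Monocyte and lymphocyte chemoattractants were higher for 10 and lower for 2 of 21 measured genes, with a median of 0.90, also above all 10000 random lists. In this list Cxcl13 and Ccl9 were 9.61-fold (9.33 to 9.89) and 11.3-fold (7.20 to 18.8) higher, whereas the monocyte attractant Ccl2 was close in both libraries, at 1152 and 1169 CPM.

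Some genes of lipid handling and fat cell formation were higher over the class as a whole, with low levels of the genes specific to mature adipocytes. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), which encodes lipoprotein lipase, stood at 192 CPM in the control library and 622 CPM in the IMQ library, 3.23-fold (3.17 to 3.30) higher, and the lipid carrier Apod was 7.52-fold (7.42 to 7.63) higher. Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399), the main transcription factor of adipogenesis, had 1.47 (1.20 to 1.78) CPM in control cells and 3.49 (3.01 to 4.03) CPM in IMQ cells. Fabp4 and Plin2, which encode a fatty acid carrier and a lipid droplet coat protein, were 2.72-fold (2.46 to 3.01) and 2.82-fold (2.68 to 2.97) higher. Adipoq, which encodes the adipocyte hormone adiponectin, had 0.918 against 1.95 CPM, Retn 0.212 against 3.64 CPM and Cidec 0.395 against 2.06 CPM. A single IMQ cell held 99 of 105 Adipoq, 193 of 196 Retn, 109 of 111 Cidec and 578 of 1202 Fabp4 UMIs; without the cell with most UMIs of each gene in each library, a setting added after the data were seen, their log2 ratios were -1.54, 0.98, -0.19 and 1.61. The transcription factors Cebpa and Cebpb had 11.8 against 21.4 CPM and 956 against 944 CPM. Of 30 measured adipogenic and lipid genes, 11 were higher and 0 lower, with a median log2 ratio of 0.51, at percentile 98.8 of the random lists. With the same cells left out for each gene, 9 were higher and 1 lower, with a median of 0.39. Within the fibroblast subclusters that both libraries share, numbered 0, 2, 3, 5 and 10, the list lay at 0.13, -0.01, 0.21, -0.01 and -0.17 relative to all genes. Pparg was above 0 in 1 of these 5, with a median log2 ratio of -0.60, Fabp4 in 2, with -0.17, and Lpl in 3, with 0.02. Over the cells of these subclusters summed together, the list median was 0.41 and Plin2 had a log2 ratio of 0.54. Subcluster 0, which held 673 of 1202 Fabp4 UMIs of the class in the IMQ library, 578 of them in that single cell, took 5.94% of control and 14.1% of IMQ cells of the class.

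Markers of adipocyte precursors had a slightly negative median over the class. Over the cells of the shared subclusters it was 0.21, and neither value is relative to all genes. Of the 18 precursor markers 1 was higher by 2-fold, namely Dlk1 at 0.381 against 1.58 CPM, 0 were lower, and the median log2 ratio of -0.16 lay at percentile 0.190 of the random lists. The stem cell antigen gene Ly6a had 1419 against 2169 CPM, the growth factor receptor gene Pdgfra 161 against 290.4 CPM, Cd34 785 against 482 CPM, Wnt2 33.2 against 21.2 CPM, and the adhesion molecule and preadipocyte marker Icam1 199 against 165 CPM. By subcluster the median of the precursor list ran from -0.33, at percentile 0.480 of the random lists, in subcluster 10 to 0.50, at percentile 99.4, in subcluster 3. Relative to all genes it was -0.20, -0.06, 0.22, 0.08 and -0.34 in subclusters 0, 2, 3, 5 and 10. In these lists, 8 of 18 precursor markers and 14 of 31 adipogenic and lipid genes are also cell type markers that helped to name clusters.

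**Figure D2:**
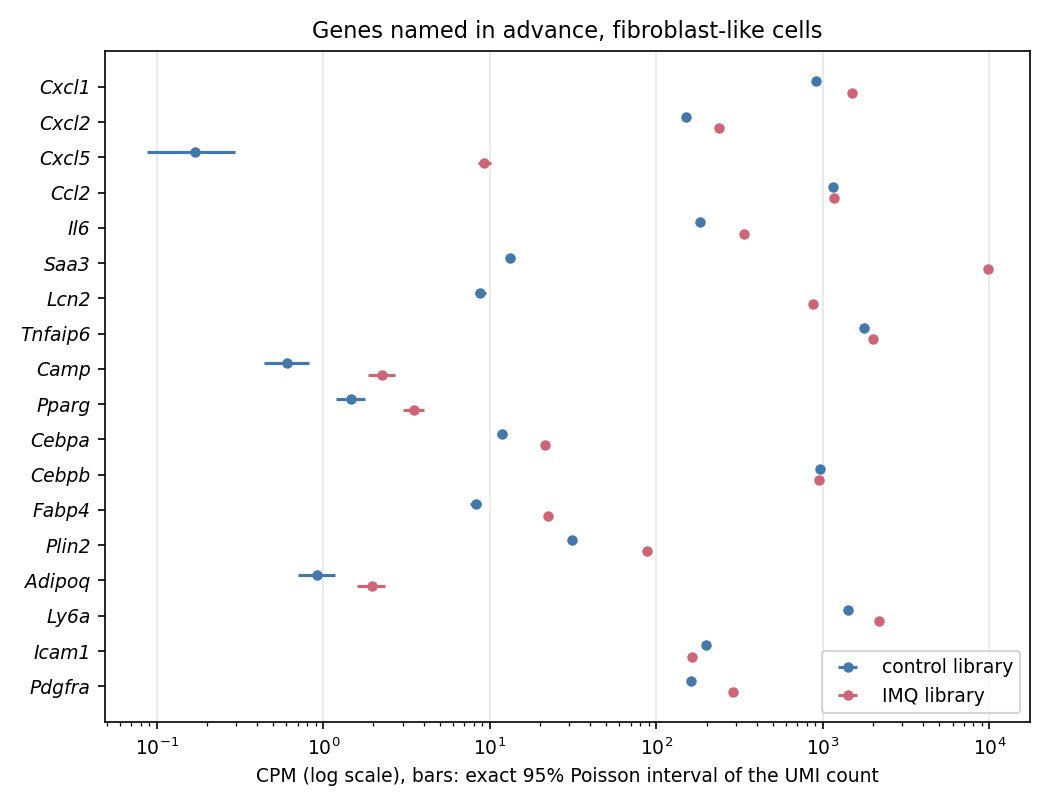
CPM of the 18 genes named in advance in fibroblast-like cells of the control and IMQ libraries, on a log axis, with exact 95% Poisson intervals of the UMI counts as bars. Saa3 and Lcn2 lie furthest apart among the abundant genes, at 13.3 against 9736 CPM and 8.77 against 877 CPM, while Ccl2 and Cebpb nearly coincide.

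The matrix genes split by gene. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) and Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544), the chains of type I collagen, were 3.87-fold (3.86 to 3.88) and 3.73-fold (3.72 to 3.74) lower in the IMQ library, at 45504 against 11746 CPM and 55404 against 14868 CPM. Col3a1 had 25475 against 15641 CPM, whereas Tnc, which encodes the injury-associated matrix protein tenascin C, was 12.3-fold (11.5 to 13.2) higher, Col12a1 4.21-fold (3.99 to 4.44) higher, Efemp2 3.75-fold (3.62 to 3.89) higher and the calcification inhibitor Mgp 12.9-fold (12.6 to 13.3) higher. Over 33 collagen and matrix genes, 8 were higher and 4 lower, and the median log2 ratio of 0.28, or 0.01 relative to all genes, lay at percentile 91.6 of the random lists. Among matrix remodelling enzymes and their inhibitors, 5 were higher and 1 lower of 28, with a median of -0.01, at percentile 3.35 of the random lists. In this list the metalloproteinase inhibitor Timp1 was 11.6-fold (11.2 to 11.9) higher, Mmp11 11.5-fold (10.4 to 12.6) higher, Mmp19 had 28.7 against 71.9 CPM and the hyaluronan synthase Has2 was 2.30-fold (2.19 to 2.41) lower.

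Several signalling genes were lower over the class as a whole in the IMQ library. The neuropeptide gene Gal (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544) was 54.7-fold (43.0 to 70.6) lower in the IMQ library, at 68.0 against 1.24 CPM, the aldehyde dehydrogenase gene Aldh3a1 13.7-fold (12.1 to 15.6) lower and the stanniocalcin gene Stc1 9.07-fold (8.23 to 10.0) lower. Grem1, which encodes a BMP antagonist, was 6.04-fold (5.70 to 6.40) lower, Tgfbi 3.91-fold (3.83 to 3.99) lower, Wnt5a 2.85-fold (2.68 to 3.04) lower and Ctgf 5.27-fold (5.06 to 5.50) higher. Over the cells of the shared subclusters Grem1 had the opposite direction, with a log2 ratio of 1.58 in place of -2.59, Stc1 had -0.63 in place of -3.18, and Gal, Aldh3a1 and Tgfbi had -2.36, -1.30 and -1.27. The Wnt, BMP and TGF-beta list held 3 higher and 5 lower genes of 33, with a median log2 ratio of -0.41, below all 10000 random lists. The other genes named by the rule were Chl1, a cell adhesion gene, at 7.81 against 107 CPM, and, on the lower side, Cdh4 (98.0 against 17.4 CPM), Ppp1r14a (100.4 against 21.7 CPM), Ndufa4l2 (419.9 against 94.6 CPM), Fam180a (53.7 against 11.5 CPM) and Igfbp5 (1408 against 376 CPM). In the shared subclusters Ppp1r14a, Ndufa4l2 and Igfbp5 had log2 ratios of -0.14, -0.21 and -0.51.

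Cell cycle genes were higher in 25 and lower in 0 of 32 cases, with a median log2 ratio of 2.53, above all 10000 random lists. The mitotic genes Ube2c and Cenpf were 17.9-fold (14.0 to 23.3) and 14.6-fold (10.6 to 20.5) higher, and Mki67 had 1.60 against 12.8 CPM. Over the cells of the shared subclusters the cell cycle median was 2.17. In subcluster 5, whose leading genes include Ube2c, Cenpf and Mki67, 27 of 32 were higher, with a median of 2.04. Subclusters 0, 2, 3 and 10 had 5 of 17, 1 of 14, 11 of 23 and 1 of 12 higher. Their medians were 0.93, 0.68, 1.29 and 0.40. Complement genes were higher in 8 of 18 cases and lower in 0, with a median of 0.76, at percentile 99.9 of the random lists. Cfb, a component of the alternative pathway, was 7.46-fold (6.96 to 8.01) higher and C4b 3.07-fold (3.02 to 3.12) higher. The IL-17 and NF-kB response list had 7 higher genes, led by Saa3 and Lcn2, and 1 lower gene of 26, with a median of 0.21, at percentile 60.6 of the random lists, that turned to -0.06 relative to all genes. For resolution and inhibition of inflammation the counts were 2 higher and 1 lower of 23, with a median of 0.19, at percentile 51.3 of the random lists, that turned to -0.08 relative to all genes. In that list Tnfaip6, which encodes the anti-inflammatory hyaluronan-binding protein TSG-6, had 1759.9 against 2009.6 CPM, Il18bp was 2.62-fold (2.15 to 3.21) higher, Gas6 2.62-fold (2.57 to 2.67) higher and Mertk had 16.8 against 7.55 CPM. Type I interferon response genes gave 4 higher, 1 lower and 26 with neither, with a median of 0.38, at percentile 83.7 of the random lists. Cxcl10 was 3.22-fold (3.13 to 3.31) higher and Usp18 2.52-fold (2.29 to 2.78) lower. Antigen presentation had 1 higher and 1 lower gene of 20 and a median of 0.41, at percentile 84.4 of the random lists, and hypoxia and glycolysis 2 higher genes of 27, among them Adm at 76.0 against 283 CPM, and a median of 0.34, at percentile 86.0 of the random lists, that turned to -0.12 in the shared subclusters.

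Relative to the all-gene median, the antimicrobial list stood at 3.09, cell cycle at 2.26, neutrophil chemoattractants at 1.24, monocyte and lymphocyte chemoattractants at 0.62, complement at 0.48, adipogenic and lipid genes at 0.24, interferon at 0.10, precursor markers at -0.43 and Wnt, BMP and TGF-beta at -0.68. Dissociation stress genes had a median of 0.29 and 0.02 relative to all genes. Markers of neutrophils, which can enter as free RNA, had a median of 3.81, or 0.40 with free RNA subtracted, with S100a9 at 0.395 against 33.4 CPM, and markers of red blood cells and muscle one of 1.09. The value of 0.40 had its middle members at the floor of 3 counts in both libraries. It equals the ratio of the UMI totals of the class and is no measure of expression. Fibroblast markers themselves had one of 0.10, and keratinocyte markers one of 0.16.

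The class was held by different clusters in the 2 libraries. Clusters 5, 6, 9 and 11 held most control fibroblast-like cells, with 21.2%, 13.5%, 22.5% and 11.3% of them, against 27.2%, 14.1%, 17.2% and 17.0% of IMQ cells in clusters 2, 10, 20 and 0. Saa3, Saa1, Hp and Cxcl12 were also among the leading genes of cluster 2, Gal, Col1a1, Col1a2 and Cdh4 of cluster 5, and Stc1, Grem1 and Fam180a of cluster 11, so class values and clusters were not independent, and a cluster held by 1 library may be that library and not a cell type. After the fibroblast-like cells were clustered again, 5 of 13 subclusters held at least 50 cells of each library, together 1589 control cells (23.2%) and 1499 IMQ cells (39.8%). These were subclusters 0 and 2, which stayed unnamed, 3 (dermal papilla-like), 5 (dermal sheath or myofibroblast-like) and 10 (reticular-like). Subclusters 4, unnamed, with 27.2% of control cells, and 6, interstitial progenitor-like, with 23.7%, held 5 and 15 IMQ cells, while subclusters 1, reticular-like, with 37.3% of IMQ cells, and 11, unnamed, with 19.9%, held 5 and 13 control cells. Subcluster 11 had 9 of 10 interstitial progenitor markers detected, but its leading genes favoured another subtype. In the first clustering, clusters 1, 9 and 10 were interstitial progenitor-like. They held 441, 1544 and 107 control cells and 35, 244 and 532 IMQ cells, so loss of such cells cannot be read from subcluster 6 alone.

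Within the 5 shared subclusters, several acute-phase genes were again higher in the IMQ library. Saa3, Saa1, Prg4, Timp1 and Cxcl12 were higher by the 2-fold rule in 5 of 5 subclusters, with median log2 ratios of 8.93, 5.66, 3.89, 3.19 and 2.53, and Lcn2 and Hp in 4 of 5, with medians of 7.21 and 5.90. Antimicrobial genes had list medians between 3.02 in subcluster 0 and 4.81 in subcluster 2. Neutrophil chemoattractants had medians of 2.59, 2.44 and 2.30 in subclusters 2, 3 and 5, and of 0.12 and -0.38 in subclusters 0 and 10. Cebpb, Tnfaip6 and Icam1 had log2 ratios below 0 in all 5, with medians of -0.66, -0.55 and -1.03, and Icam1 met the 2-fold rule in 3 of them. Interferon genes had medians of -0.43, -0.62 and -0.41 in subclusters 0, 2 and 10, and of 0.27 and 0.45 in subclusters 3 and 5. Collagen and matrix genes were higher in 16 of 32 cases in subcluster 3 and in 18 of 33 in subcluster 5, both above all 10000 random lists. Relative to all genes their medians were 0.72 and 1.03 there, and -0.07, 0.03 and 0.10 in subclusters 0, 2 and 10. Over the cells of the shared subclusters summed together, a setting added after the data were seen, Col1a1 and Col1a2 had log2 ratios of -0.57 and -0.57 in place of -1.95 and -1.90, Lcn2 3.20 in place of 6.64, and Stc1 -0.63 in place of -3.18. In the same cells Grem1 had the opposite direction, with 1.58, as did Pparg, with -0.11, and Tnfaip6, with -0.74. The median of the list of precursor markers turned to 0.21 there, a value not relative to all genes. Relative to them it ran from -0.34 to 0.22 by subcluster. The medians of 4 other lists also turned, to -0.12 for hypoxia and glycolysis, -0.05 for resolution, 0.37 for matrix remodelling and -0.0051 for IL-17 and NF-kB.

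Keratinocyte-like cells of the IMQ library had higher transcripts of hyperplastic epidermis and lower transcripts of the cornified layers. S100a8 and S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), the chains of the antimicrobial protein calprotectin, had 0.995 against 2595 CPM and 9.93 against 2977 CPM in the control and IMQ libraries. Krt6a (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307) and Krt6b, keratins of wounded and hyperproliferative epidermis, were 52.6-fold (49.6 to 55.9) and 46.8-fold (42.7 to 51.4) higher, the serpin gene Serpinb3a was 87.1-fold (64.6 to 120.4) higher, and 2610528A11Rik was 78.8-fold (65.7 to 95.3) higher. Krt77 (ENSMUSG00000067594, chromosome 15, 101858731 to 101869705), a keratin of the suprabasal layers, was 408-fold (383 to 435) lower, at 5834 CPM in the control library and 14.3 CPM in the IMQ library, and Flg2, a filaggrin family gene of the barrier, was 313-fold (205 to 507) lower. Lce1m, a gene of the cornified envelope, was counted at 2291 UMIs in the control library and 1 in the IMQ library, and 2310050C09Rik, Sema3d and Tesc had 120.2 against 0.241 CPM, 59.8 against 0.392 CPM and 109.9 against 0.860 CPM. Of these Lce1m UMIs 2069 lay in 1 control cell, and Lce1m then had 222 and 0 UMIs. Of 40 measured activation genes, 27 were higher and 4 lower, with a median log2 ratio of 2.15, above all 10000 random lists. Krt16 was 10.2-fold (9.91 to 10.5) higher, the cytokine Il24 158-fold (67.4 to 486) higher and the cornified envelope gene Sprr2b, with 0 control UMIs, at least 365-fold higher. The differentiation list was the reverse, with 2 higher and 23 lower of 31 genes and a median of -2.11, below all 10000 random lists. Krt10 was 4.04-fold (4.01 to 4.06) lower and Lor 30.9-fold (29.7 to 32.1) lower, while Krt1 had 3621 against 3232 CPM and Krt2 was counted at 59 and 1 UMIs.

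Other gene groups were also compared in the keratinocyte-like class. Neutrophil chemoattractants were higher in 6 of 9 cases and lower in 0, with a median of 1.89, above all 10000 random lists. Cxcl2 had 24.0 against 89.2 CPM, Cxcl1 had a log2 ratio of 2.32, and Cxcl3 was counted at 1 and 820 UMIs, a ratio of 447-fold (80.1 to 17690.4). Antimicrobial genes gave 15 higher and 2 lower of 19, with a median of 2.58, above all 10000 random lists, that was 1.40 with free RNA subtracted. The defensin gene Defb14 was counted at 1 and 214 UMIs, whereas Wfdc21 was 40.9-fold (35.6 to 47.3) lower. Basal and hemidesmosome genes gave 6 higher and 1 lower of 21 and a median of 0.32, at percentile 98.2 of the random lists, with the stem cell gene Lgr5 7.18-fold (6.03 to 8.62) higher, Postn 3.78-fold (3.62 to 3.95) and Mt1 3.07-fold (3.03 to 3.10) higher. The 1 lower gene, Sparc, had 723 CPM in the control library, where free RNA would give 801 CPM. Hypoxia and glycolysis genes gave 10 higher and 1 lower of 28, with a median of 0.67, above all 10000 random lists, and cell cycle genes 9 higher and 0 lower of 32, with a median of 0.90, above all 10000 random lists. The IL-17 and NF-kB list had a median of 0.12 (7 higher and 3 lower of 27; at percentile 75 of the random lists), with Mmp13 39.6-fold (15.3 to 146) and Steap4 9.52-fold (8.05 to 11.3) higher, and the interferon list one of -0.03 (2 higher and 3 lower of 23; at percentile 37.7 of the random lists), with Usp18 12.7-fold (7.94 to 21.5) lower. Of 290 Mmp13 UMIs of the IMQ library 208 lay in 1 cell. Within this class 42.7%, 30.9%, 10.2% and 8.78% of control cells were in clusters 7, 26, 8 and 16, and 35.8%, 32.3%, 25.5% and 5.43% of IMQ cells in clusters 15, 23, 24 and 36, so these values compare different clusters. Clusters 24 and 36 were hair follicle or sebaceous keratinocyte-like and held 2.91% and 0.247% of control cells of the class, while the other 6 were interfollicular or basal keratinocyte-like. Krt6b and Serpinb3a led cluster 15, Lce1m cluster 16 and Krt77 and Flg2 cluster 8. At a Leiden resolution of 2, which left 527 control and 60 IMQ cells unnamed, the log2 ratio of the keratinocyte-like share was 1.06 in place of 0.64, and a pseudocount of 5 CPM gave a median of 1.03 for the activation list.

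T cell-like cells of the IMQ library held more transcripts of type 17 cytokines. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047), an epithelial growth and defence cytokine, had 23.9 CPM in the control library and 1430.2 CPM in the IMQ library, 59.9-fold (41.1 to 91.1) higher, and Il17f and Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) were 8.84-fold (7.94 to 9.87) and 5.18-fold (4.88 to 5.51) higher. Cd163l1, a gene of IL-17-producing gamma delta T cells, was 5.18-fold (4.31 to 6.28) higher, and 11 of 22 genes of IL-17-producing T cells were higher and 0 lower, with a median of 0.99, above all 10000 random lists. The list of type 1, type 2 and regulatory genes had 3 higher and 10 lower genes of 22 and a median of -0.83, below all 10000 random lists, with the interferon gamma gene Ifng at 33.6 against 5.15 CPM and Il13 at 72.5 against 32.8 CPM. The higher members were the granzyme genes Gzmc and Gzmb, 27.8-fold (10.7 to 103) and 15.8-fold (8.49 to 33.4) higher, and the inhibitory receptor gene Pdcd1, 6.24-fold (4.60 to 8.65) higher. With members of at least 100 UMIs, the median of that list was 0.05, on the other side of 0. Cell cycle genes were higher in 20 of 32 cases and lower in 0, with a median of 1.34, above all 10000 random lists, and the histone gene Hist1h1b had 17.7 against 252 CPM. Ctla2a, a cysteine protease inhibitor gene, was 5.87-fold (5.47 to 6.31) lower, and Tnfsf11, Cd27, Klf4, Ctla2b and Pi16 had 87.5 against 10.8 CPM, 99.0 against 16.9 CPM, 576 against 126 CPM, 226 against 49.6 CPM and 103 against 17.3 CPM, while Apod had 6.19 against 106 CPM. Of 226 Apod UMIs 198 lay in 1 IMQ cell and of 116 Pi16 UMIs 99 in 1 control cell, and Apod had a log2 ratio of 0.92 with at most 5% mitochondrial UMIs and Pi16 -0.15 with doublets kept. Interferon genes had a median of -0.35 (1 higher and 0 lower of 15; at percentile 3.03 of the random lists).

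Natural killer-like cells showed higher granzyme transcripts, with Gzmb 4.72-fold (3.75 to 5.99) and Gzma 3.88-fold (3.57 to 4.22) higher in the IMQ library. Ly6a was 8.71-fold (4.71 to 17.9) higher and the chemokine gene Ccl1 12.4-fold (8.37 to 19.2) higher, although Ccl1 had a log2 ratio of -2.18 with each library clustered on its own and Ly6a 0.29 with doublets kept. S100a9 and S100a8, neutrophil transcripts, had 0 control UMIs and 409 and 259.6 CPM in the IMQ library. Of these UMIs 259 of 274 and 156 of 174 lay in 1 cell. Cell cycle genes were higher in 17 of 27 cases, with a median of 1.38, above all 10000 random lists, and interferon genes had a median of 0.34 (1 higher of 12; at percentile 90.9 of the random lists). The orphan receptor gene Nr4a2 was 2.76-fold (2.37 to 3.21) lower, and Aff1, Spry2, Cdkn1a, Ppp1r16b and Irf2bp2 were 3.43-, 2.72-, 2.82-, 2.62- and 2.99-fold lower.

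Macrophage/monocyte-like cells, compared after the requirement of 100 cells per library had been relaxed to 30, had far lower transcripts of resident macrophages in the IMQ library. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a gene of alternatively activated macrophages, had 15169 CPM in the control library and 1.53 CPM in the IMQ library, with 5457 and 4 UMIs. Folr2 and Lyve1, genes of perivascular resident macrophages, were 31.5-fold (25.1 to 39.9) and 59.5-fold (37.7 to 98.5) lower, and Mgl2, Fcna and Ltc4s had 675 against 15.3 CPM, 575 against 3.83 CPM and 434 against 11.9 CPM. Of 20 measured resident macrophage genes, 20 were lower, with a median of -3.28, below all 10000 random lists. The class held 77 control and 503 IMQ cells, with 359748 and 2612336 UMIs. Lower expression per cell and a different mix of cells in the class therefore cannot be told apart for this list. Inflammatory genes were higher in 23 and lower in 1 of 32 cases, with a median of 2.00, above all 10000 random lists. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes arginase, had 0 control UMIs and was at least 58.3-fold higher, and Chil3 was 77.7-fold (35.7 to 212) higher. Saa3 was counted at 1 and 2899 UMIs, a ratio of 399-fold (71.6 to 15774), and Ifitm1 at 3 and 2503, a ratio of 115-fold (39.3 to 558). Neutrophil chemoattractants were higher in 7 of 8 cases, with a median of 2.35, above all 10000 random lists, and Il1b, Cxcl2 and Cxcl1 were 5.84-fold (5.32 to 6.44), 3.75-fold (3.53 to 3.98) and 7.09-fold (5.42 to 9.46) higher. S100a8 and S100a9 were at least 69.8-fold and at least 51.1-fold higher from 0 control UMIs, although they had log2 ratios of 0.40 and -0.88 with each library clustered on its own, and S100a9 7.46 there without the 8 neutrophil-like control cells that had entered the class.

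Several other lists were lower in the IMQ macrophage/monocyte-like cells. Complement genes were lower in 10 of 14 cases, with a median of -1.59, below all 10000 random lists. C1qa, which encodes a chain of the first complement component, was 3.32-fold (3.10 to 3.56) lower and C4b 13.3-fold (10.3 to 17.1) lower. Interferon genes were higher in 1 and lower in 12 of 26 cases, with a median of -0.96, at percentile 0.0100 of the random lists, and Rtp4 and Oasl2 were 5.61-fold (3.48 to 8.98) and 4.84-fold (3.29 to 7.07) lower. Antigen presentation had 0 higher and 6 lower genes of 21 and a median of -0.88, below all 10000 random lists, with H2-Aa 3.72-fold (3.47 to 3.98) lower. For resolution the median was -0.41 (4 higher and 7 lower of 20; at percentile 2.48 of the random lists), with Gas6 15.5-fold (12.1 to 19.9) lower and the interleukin-1 inhibitors Il1rn and Il1r2 10.6-fold (4.09 to 39.0) and 13.2-fold (4.46 to 64.3) higher. Monocyte and lymphocyte chemoattractants had a median of 0.12 (3 higher and 5 lower of 15; at percentile 38.9 of the random lists), with Ccl8 and Ccl24 14.7-fold (13.4 to 16.2) and 10.6-fold (8.24 to 13.7) lower. Hypoxia and glycolysis genes were higher in 9 of 24 cases, with a median of 0.89, above all 10000 random lists, and the lactate transporter Slc16a3 was 5.32-fold (2.67 to 12.4) higher. Cell cycle genes had a median of 0.62 (1 higher and 1 lower of 20; at percentile 99.4 of the random lists). The class had 77 control cells, and size factors moved its all-gene median of -0.09 by 0.11. With each library clustered on its own, the medians of interferon and complement genes were -0.09 and 0.07. With the dendritic-like cells as the only ones added to the class they were -0.11 and 0.04. Separate clustering added 120 control but 15 IMQ dendritic-like cells, so it altered mainly the control side. The median of cell cycle genes was -0.38 at a resolution of 0.5, where the class took in all dendritic-like cells.

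Mfge8, a phagocytosis gene that was also a Langerhans cell marker here, was 15.9-fold (13.6 to 18.8) higher in dendritic-like cells of the IMQ library, and Ifitm1 was 38.0-fold (28.4 to 52.0) higher. Cd209d, Mgl2 and Mrc1, lectin genes of dermal myeloid cells, were 9.70-fold (7.56 to 12.6), 6.92-fold (5.82 to 8.26) and 6.39-fold (4.23 to 9.94) lower, and Ear2, Ccl2 and Lyz2 were 11.1-fold (7.34 to 17.4), 11.6-fold (7.27 to 19.6) and 5.97-fold (5.44 to 6.56) lower. Antigen presentation genes had a median of 0.36 (2 higher and 0 lower of 22; at percentile 99.4 of the random lists), or 0.24 relative to the all-gene median of 0.12, with the costimulatory genes Cd80 and Cd40 2.53-fold (1.36 to 5.08) and 2.02-fold (1.31 to 3.22) higher. Zmynd15 had 1 and 216 UMIs, while S100a9, S100a8 and Jchain had 0 control UMIs and 396, 338 and 151 CPM in the IMQ library. Jchain had log2 ratios of -0.58 and -0.55 when at most 5% or 20% mitochondrial UMIs were allowed. With 0 control UMIs, such values arise when floors of 3 counts stand in for counts of 0, and they show no reversal. All 199 Jchain UMIs lay in 1 IMQ cell, 494 of 523 S100a9 and 416 of 446 S100a8 UMIs in another, and 127 of 153 control Ccl2 UMIs in 1 control cell; Cd40 no longer met the rule without its highest cell. Interferon and cell cycle genes had medians of 0.00 and -0.09, at percentile 21.3 of the random lists and at percentile 6.34 of the random lists.

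Neutrophil-like cells of the IMQ library expressed inflammatory mediators at high levels, and no gene was compared with the control library, which held 8 such cells. S100a9 and S100a8 stood at 109699 (109034 to 110367) and 69764 (69234 to 70297) CPM. Cxcl2 had 28036 CPM, Il1b 13242 CPM, Ccl3 1609 CPM, the prostaglandin synthase gene Ptgs2 1191 CPM, and the granule genes Lcn2 and Ngp 5532 and 1175 CPM. Camp had 304 (270.2 to 342) CPM. Of 31 neutrophil activation genes, 30 had at least 20 UMIs, with a median of 465 CPM over the list. For antimicrobial and acute-phase genes, which include S100a8 and S100a9, these numbers were 13 of 26 and 104 CPM, and for hypoxia and glycolysis genes 24 of 28 and 128 CPM.

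Endothelial-like cells of the IMQ library expressed leukocyte adhesion genes at higher levels, again in a class with fewer than 100 control cells. Selp (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026), which encodes the P-selectin that starts leukocyte rolling, had 24.7 CPM in the control library and 681 CPM in the IMQ library, 27.5-fold (12.6 to 75.1) higher. Sele and Ackr1, an E-selectin and a chemokine-binding receptor of venules, were counted at 1 and 2 UMIs in the control library and 769 and 523 in the IMQ library, ratios of 80.3-fold (14.4 to 3175) and 27.3-fold (7.52 to 226). The activation and adhesion list had 9 higher and 1 lower genes of 26 and a median of 0.64, at percentile 99.8 of the random lists. Icam2 was 7.29-fold (3.81 to 16.0) higher, whereas Icam1 had 322 against 454 CPM and Vcam1 24.7 against 54.7 CPM. Cell cycle genes were higher in 21 and lower in 1 of 32 cases, with a median of 1.44, above all 10000 random lists. Ube2c and Hist1h2ap were at least 14.8-fold and at least 7.52-fold higher from 0 control UMIs, and Igfbp3 was 11.5-fold (6.56 to 22.3) higher. Interferon genes were lower in 9 and higher in 1 of 24 cases, with a median of -0.59, at percentile 0.110 of the random lists, and antigen presentation genes had a median of 0.69 (3 higher of 15; at percentile 98.2 of the random lists). Cxcl12 was 5.70-fold (4.73 to 6.86) lower, Nr4a2 had 404 against 33.6 CPM, and Ccnd2, Ppp1r10, Clu and Adamts4 were 8.12-, 8.17-, 6.84- and 6.23-fold lower. Relative to the all-gene median of 0.17, the adhesion, cell cycle, interferon and antigen presentation lists stood at 0.48, 1.28, -0.75 and 0.53.

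In lymphatic endothelial-like cells Lcn2 was 3.25-fold (2.92 to 3.62) higher in the IMQ library, at 706 against 2293 CPM, and the endothelin receptor gene Ednrb 4.04-fold (2.99 to 5.59) higher. Gja4, Adamts5 and Ctla2a were 8.56-, 4.34- and 3.08-fold higher, and Ifitm1 had 2 and 365 UMIs. Tgfbi and Tgfb2 were 5.97-fold (4.63 to 7.72) and 5.78-fold (4.27 to 7.87) lower, and Procr, Nr4a2, Syne1 and Pxdc1 were 2.87-, 3.03-, 2.49- and 2.37-fold lower. Interferon genes had a median of 0.88 (7 higher and 0 lower of 22; above all 10000 random lists), or 0.72 relative to the all-gene median of 0.16, and cell cycle genes one of -0.14 (at percentile 4.07 of the random lists).

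Over the pericyte/smooth muscle-like class as a whole, interferon-induced and cell cycle genes were higher in the IMQ library. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), an interferon-induced attractant of T cells, had 0 control UMIs and 198 (181 to 215) CPM in the IMQ library, at least 171-fold higher, although its log2 ratio was -1.41 at a Leiden resolution of 2. Of its 514 UMIs 496 lay in 1 of 220 cells, and the other 18 gave a log2 ratio of at least 2.58. With 0 control UMIs in the class, the value of -1.41 rests on the floor of 3 counts and shows no reversal. Of 21 measured interferon genes, 10 were higher and 0 lower, with a median of 0.90, above all 10000 random lists. In the larger of the 2 clusters that made up the class the median was 0.57. At a resolution of 2 it was 0.86 over the class and 0.27 in the larger of its 2 clusters. Ifit3 and Rtp4 were 5.67-fold (2.35 to 16.5) and 5.00-fold (1.88 to 16.7) higher, from 6 and 5 control UMIs. Cell cycle genes were higher in 19 of 26 cases, with a median of 2.92, above all 10000 random lists, and 2810417H13Rik was at least 47.0-fold higher. At a resolution of 2, which left 274 control and 165 IMQ cells, the median of cell cycle genes was 0.10 and 2810417H13Rik had a log2 ratio of 0.59. The matrix genes Ctgf, Timp1 and Thbs4 had 17.7 against 671 CPM, 5.00 against 165 CPM and 0 against 110.4 CPM, and the muscle actin gene Acta1 18.1 against 326 CPM. Single IMQ cells held 282 of 287 Thbs4, 473 of 849 Acta1 and 25 of 34 Ifit3 UMIs, and without the highest cell of each library Thbs4 and Ifit3 no longer met the 2-fold rule. Thbs4 also had log2 ratios of 0.71 with at least 500 genes detected and 0.99 with separate clustering, in place of at least 6.58. Igfbp2 was 13.6-fold (11.7 to 15.9) lower, and Tnnt1, Nr4a2, Plekhh2, Tiparp and Chrdl1 were 11.1-, 7.66-, 8.17-, 5.06- and 5.78-fold lower. In this class free RNA was estimated at 7.68% of control and 13.3% of IMQ UMIs, and fibroblast markers had a median of 1.05, with Lum at 17.3 against 149 CPM. The median of fibroblast markers was 3.76 with free RNA subtracted and -0.14 when doublets were kept.

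Schwann-like cells had higher Apod, Ifitm3 and Serpina3n, an acute-phase protease inhibitor gene, by 3.89-fold (3.56 to 4.26), 4.41-fold (3.67 to 5.34) and 5.27-fold (3.98 to 7.10). Igfbp6 and Krt79 were 18.1-fold (9.70 to 38.3) and 6.56-fold (4.43 to 10.1) higher, and Igfbp4 was counted at 3 and 111 UMIs. Interferon genes were higher in 4 of 13 cases, with a median of 0.45, at percentile 98.6 of the random lists, and cell cycle genes had a median of 0.00, at percentile 32.5 of the random lists. The stress genes Hspa1b, Gadd45b, Nr4a2 and Ppp1r15a were 2.47-, 2.23-, 2.21- and 2.23-fold lower. Cst6 had 549 against 31.2 CPM, but log2 ratios of 1.30, 0.49 and 1.33 with at least 500 genes per cell, with at most 5% mitochondrial UMIs and with separate clustering. In 1 control cell lay 307 of its 314 UMIs, and single IMQ cells held 150 of 244 Igfbp6 and 168 of 247 Krt79 UMIs.

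The technical lists also differed between the libraries in most classes. Dissociation stress and immediate early genes had medians of -0.38 in keratinocyte-like, -0.48 in T cell-like, -0.56 in natural killer-like, -0.44 in pericyte/smooth muscle-like, -0.54 in macrophage/monocyte-like and -0.60 in endothelial-like cells, all at or below percentile 0.14 of the random lists, and of -0.05, -0.10 and 0.00 in dendritic-like, Schwann-like and lymphatic endothelial-like cells. Neutrophil markers had medians of 3.52, 3.93, 5.43, 4.59, 5.25, 2.53, 2.89, 1.11 and 2.10 in the keratinocyte-like, T cell-like, natural killer-like, dendritic-like, pericyte/smooth muscle-like, Schwann-like, macrophage/monocyte-like, endothelial-like and lymphatic endothelial-like classes. In the same order, fibroblast markers had medians of -1.62, -1.59, -2.89, -1.03, 1.05, 0.23, -1.01, 0.25 and -2.05, keratinocyte markers of -0.63, -0.70, -1.02, -0.47, -0.42, 0.09, 0.10, 0.63 and -0.50, and red blood cell and muscle markers of 2.72, -0.93, 8.25, -5.66, 4.86, -5.81, 2.48, 1.54 and 1.03. With free RNA subtracted, the medians of neutrophil markers were 5.29 in natural killer-like, 4.10 in dendritic-like and 2.11 in macrophage/monocyte-like cells, and lay between -3.26 and 0.74 in the other 6 classes. Of these 6, all but the keratinocyte-like class (0.74) had the middle members at the floor of 3 counts in both libraries. Their values equal the ratio of the UMI totals of the class. With the highest cell of each library left out for each gene, red blood cell and muscle markers turned to 1.18 in T cell-like, 1.78 in dendritic-like, 2.13 in Schwann-like and -0.16 in endothelial-like cells. Neutrophil markers were then 2.16 in natural killer-like, 2.44 in dendritic-like and -0.26 in endothelial-like cells, and keratinocyte markers -0.26 in the latter. Fibroblast markers turned to -0.46 in endothelial-like and -0.20 in Schwann-like cells.

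**Figure D3:**
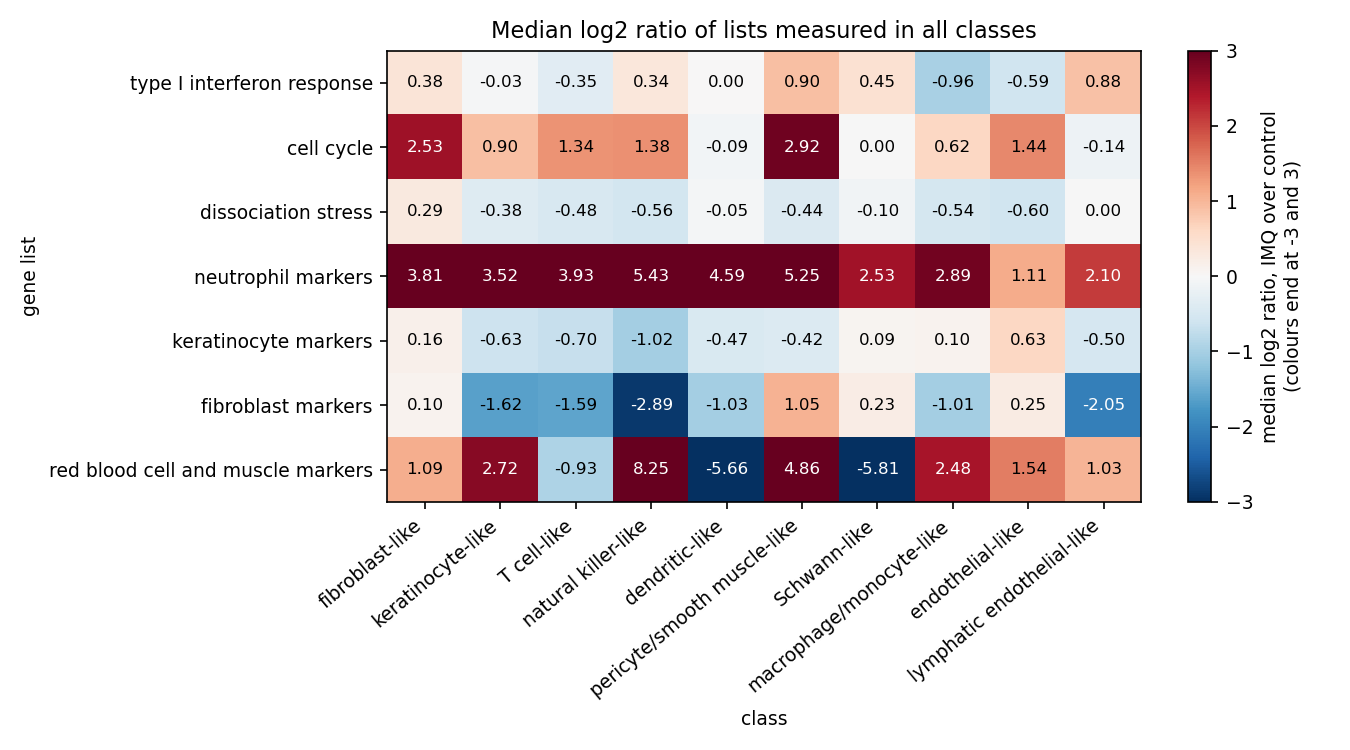
Median log2 ratio, IMQ over control, of the gene lists measured in every class, with lists as rows, classes as columns and colours that end at -3 and 3. The cell cycle row reaches 2.92 in pericyte/smooth muscle-like and 2.53 in fibroblast-like cells, and the interferon row runs from -0.96 in macrophage/monocyte-like to 0.90 in pericyte/smooth muscle-like cells.

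The UMIs of each mediator were counted by class in each library as a view of its cellular sources. Such shares depend on how many cells of a class were recovered and on their depth, and free RNA was not subtracted. Besides the genes named in advance, these genes were chosen after their values were seen. Fibroblast-like cells held 94.1% of the Cxcl1 UMIs of the control library and 84.8% of those of the IMQ library, and 97.2% and 89.8% of Ccl2. Cxcl2 lay to 74.4% in fibroblast-like cells in the control library, whereas in the IMQ library 35.5% lay in macrophage/monocyte-like, 30.9% in neutrophil-like and 14.9% in fibroblast-like cells. In the control and IMQ libraries its level was 151 and 237 CPM in fibroblast-like cells. In macrophage/monocyte-like cells it was 3122 and 11693 CPM, higher than in fibroblast-like cells in both libraries. Saa3 and Lcn2 of the IMQ library lay to 97.6% and 65.0% in fibroblast-like cells, and Camp to 70.1% in neutrophil-like cells. Of 37688 Il1b UMIs in the IMQ library, 49.5% were in macrophage/monocyte-like and 33.4% in neutrophil-like cells. The control library had 2715, of which 52.4% were in dendritic-like cells. Csf3 numbered 143 UMIs in the control library, 69.9% of them in lymphatic endothelial-like cells, and 2781 in the IMQ library, 56.8% of them in fibroblast-like cells. S100a8 of the IMQ library lay to 70.9% in keratinocyte-like and 27.3% in neutrophil-like cells, and Il17a to 99.3% and 98.2% in T cell-like cells of the control and IMQ libraries.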

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

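The patterns weighed in this part and the limits that decide them were chosen after the results were seen. So were the shared subclusters, the macrophage/monocyte-like and endothelial-like classes, the addition of dendritic-like cells alone, the values by pericyte cluster and those without the highest cell, while the other settings had been planned; the differences between classes named here were not tested. Only the classes planned for a list were considered here. Gene lists are given whose median was above 0 and above the central 95% of the random lists in 1 such class, and below 0 and below the central 95% in another. Antigen presentation genes had a median log2 ratio of 0.69 in endothelial-like and -0.88 in macrophage/monocyte-like cells. Complement genes had 0.76 in fibroblast-like and -1.59 in macrophage/monocyte-like cells. The former was -0.30 in shared subcluster 0, and 0.62, 1.28, 1.01 and 0.23 in subclusters 2, 3, 5 and 10. The latter turned to 0.070 with each library clustered on its own. That setting moved 120 control but 15 IMQ dendritic-like cells into the class. Fibroblast markers had 1.05 in pericyte/smooth muscle-like and -2.89 in natural killer-like cells, the former turning to -0.14 with doublets kept. Red blood cell and muscle markers had 8.25 in natural killer-like and -5.81 in Schwann-like cells. The value of -5.81 turned to 2.13 without the cell that held most UMIs of each gene in each library.

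Type I interferon response genes had a median of 0.90 in pericyte/smooth muscle-like and -0.96 in macrophage/monocyte-like cells; by these limits 3 of the 10 classes with a value were on the higher and 2 on the lower side. Free RNA as the whole cause is argued against by the medians after its subtraction, 0.87 and -0.97. For pericyte/smooth muscle-like cells, clustering each library on its own gave 1.04, with 36 of 220 IMQ cells no longer in the class. The larger cluster of the class had 0.57 on its own. The smaller had 1.01, from 6 measured genes in 70 control and 36 IMQ cells. At a resolution of 2 the class as a whole had 0.86 and its larger cluster 0.27, while the smaller had the same cell numbers and value. A difference in expression and a difference in which cells make up the class therefore cannot be told apart here, and a response to the treatment was not tested. For macrophage/monocyte-like cells clustering each library on its own gave -0.089, and -0.11 with the dendritic-like cells as the only ones added. This setting moved 120 control but 15 IMQ dendritic-like cells into the class, so it altered mainly the control side and decides nothing. A difference in expression and a difference in which cells make up the class were not told apart, with 77 control cells.

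Type I collagen genes were lower in fibroblast-like cells of the IMQ library, with log2 ratios of -1.95 for Col1a1 and -1.90 for Col1a2. Scaling is argued against, as the ratio nearest to 0 over both genes was -2.08 under the other scalings, and so are a few cells with very many UMIs, as it was -1.75 with each cell weighing the same. Within the shared subclusters the median was -0.40 for the gene nearer to 0, and these hold 23.2% of control and 39.8% of IMQ cells of the class. Lower expression per cell and a different mix of fibroblast-like cells therefore cannot be told apart, because most cells lie in subclusters held by 1 library.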

How the results depend on the processing

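Of the tests in this part, the restriction to shared subclusters, the classes with fewer than 100 cells, the tracing of cells between classes and the values without the highest cell were chosen only after results were seen. No paired analysis was possible because each group had 1 library. The shares of fibroblast-like, keratinocyte-like, T cell-like, macrophage/monocyte-like and neutrophil-like cells had the same sign in 40 of 40 values, with log2 ratios from -0.63 to -0.55, 0.59 to 1.06, 0.48 to 0.77, 1.51 to 2.95 and 5.33 to 6.82. The 9 list medians that answer the main comparisons had the same sign in 138 of 141 values. In 108 they stayed between the medians of their members' interval bounds, which cover counting error only. The 94 other list medians had the same sign in 1306 of 1387 values, named genes in 1762 of 1780, and the 11 other shares in 82 of 84. Genes of IL-17-producing T cells ranged from 0.76 to 1.17. Values below are log2 ratios or medians of them; unless a reason is given, the cause was not tested.

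In fibroblast-like cells, leaving out the 50 most abundant genes gave medians of 0.023 for IL-17 and NF-kB, -0.35 for precursor, 0.33 for adipogenic, 0.10 for collagen and 0.19 for interferon genes, and size factors -0.064, -0.43, 0.24, 0.0089 and 0.10, as both move all genes of the class together. In shared subclusters Grem1 had 1.58, Pparg -0.11, and the lists of IL-17 and NF-kB -0.0051, precursor 0.21, collagen 0.41, neutrophil chemoattractant 2.07 and interferon genes 0.021, over fewer cells of other subtypes. Subtracting free RNA gave 0.32 for IL-17 and NF-kB and 0.92 for neutrophil chemoattractants in fibroblast-like cells. It gave 1.45 for fibroblast markers in dendritic-like cells. For neutrophil markers it gave -0.43, -0.92, -1.96 and -0.00021 in Schwann-like, T cell-like, lymphatic endothelial-like and pericyte/smooth muscle-like cells. For red blood cell and muscle markers it gave -3.26 and -2.86 in endothelial-like and macrophage/monocyte-like cells. These markers are what the subtraction removes. The values from -0.43 to -2.86 had their middle members at the floor of 3 counts in both libraries. They equal the ratio of the UMI totals of the class and are no measure of expression. The mean over cells gave 0.12 for IL-17 and NF-kB, 0.18 for collagen, 2.60 for keratinocyte activation, -1.69 for keratinocyte differentiation, and 0.38 for red blood cell and muscle markers in T cell-like cells. A pseudocount of 5 CPM gave 0.25 for adipogenic, 1.03 for activation, -1.45 for differentiation and 0.72 for chemoattractant genes, and no minimum with a pseudocount of 1 CPM 1.06 for activation, -1.76 for differentiation and 0.78 for chemoattractants, as pseudocounts draw low genes to 0. With members of at least 100 UMIs the values were -0.29 for cell cycle in macrophage/monocyte-like cells, -2.01 for differentiation and 0.050 for type 1, type 2 and regulatory T cell genes.

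With each library clustered on its own, Ccl1 had -2.18 in natural killer-like, Cst6 1.33 in Schwann-like and S100a9 -0.88 in macrophage/monocyte-like cells. In the latter class cell cycle had -1.0, complement 0.070, neutrophil markers -0.88 and red blood cell and muscle markers -5.66, and its share had 1.51, as 120 dendritic-like, 9 basophil-like and 8 neutrophil-like control cells were then in the class. Without the 8 neutrophil-like cells S100a9 had 7.46 and neutrophil markers 4.02. Under this setting collagen had 0.26, red blood cell and muscle markers 0.60 in T cell-like and -1.13 in fibroblast-like cells, the fibroblast-like share -0.55 and the neutrophil-like share at least 6.82, against the floor for 0 control cells. A resolution of 0.5 gave -0.38 for cell cycle and -4.68 for red blood cell and muscle markers in macrophage/monocyte-like cells, 1.93 for their share, and 0.94 for red blood cell and muscle markers in T cell-like cells. A resolution of 2 gave -1.41 for Cxcl9 in pericyte/smooth muscle-like cells, 0.10 for cell cycle in the same cells, -2.49 for differentiation and 1.06 for the keratinocyte-like share. At least 500 genes per cell gave 0.71 for Thbs4 in pericyte/smooth muscle-like cells, 1.30 for Cst6, -2.04 for differentiation and 0.50 for red blood cell and muscle markers in T cell-like cells. At most 5% mitochondrial UMIs gave 0.49 for Cst6, -0.58 for Jchain in dendritic-like cells, 0.43 for fibroblast markers in macrophage/monocyte-like cells and 2.51 for the share of the latter, and at most 20% gave -0.55 for Jchain and 0.69 for fibroblast markers. List genes left out of the variable genes gave 0.66 for fibroblast markers in macrophage/monocyte-like cells. Keeping doublets gave -2.04 for differentiation, -0.14 for fibroblast markers in pericyte/smooth muscle-like cells, 0.036 for keratinocyte markers in T cell-like cells, and 0.72 and -0.92 for red blood cell and muscle markers in T cell-like and keratinocyte-like cells. No value was obtained for dendritic-like and natural killer-like classes at a resolution of 0.5, for genes of dendritic-like cells with separate clustering, for red blood cell-like cells with at least 500 genes, for melanocyte-like cells with at most 20% mitochondrial UMIs, and for 12 list medians with too few members of at least 100 UMIs. Without the cell that held most UMIs of a gene in each library, Adipoq had -1.54 and Cidec -0.19 in fibroblast-like, Jchain -0.60 in dendritic-like, Cst6 1.09 in Schwann-like and Cxcl9 2.58 and Thbs4 0.74 in pericyte/smooth muscle-like cells, as single cells held most of their UMIs. The control library held 0 UMIs of Jchain and Cxcl9 in these classes. The negative values of both genes rest on floors of 3 counts and show no reversal. In Poisson counts simulated at the UMI totals of the macrophage/monocyte-like class, 65.3% of 2.5-fold differences were recovered, against 91.9% for fibroblast-like cells. No spread between cells was simulated.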

Other observations

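The choice of genes, the lists by class, the values without Cd207 or cluster 26 and the tests on Y-linked genes in this part were chosen after the results were seen. Basophil-like cells, 9 in the control and 65 in the IMQ library, held 380 of 406 Il4 UMIs (93.6%) of the IMQ library, whereas 15 of 24 Il4 UMIs of the control library (62.5%) lay in mast cell-like cells; Il4 was also 1 of the markers that named the basophil-like cluster. For Il13, a type 2 cytokine, basophil-like cells held 47.4% of 175 UMIs of the IMQ library and T cell-like cells 75.9% of 108 UMIs of the control library. Il6 lay mostly in fibroblast-like cells, with 89.5% and 85.3%, and to 5.75% in basophil-like cells of the IMQ library. Csf3 of the IMQ library lay to 16.1% in endothelial-like and 14.3% in lymphatic endothelial-like cells, with 192 and 196 CPM in lymphatic endothelial-like cells of the control and IMQ libraries.

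Some lists that had not been planned for a class also differed in it. In Schwann-like cells complement genes were higher in 5 of 7 measured cases, with a median log2 ratio of 2.19, and antigen presentation genes in 9 of 13, with a median of 1.32, both above all 10000 random lists. Free RNA was estimated at 7.93% of control and 9.96% of IMQ UMIs of this class, and with it subtracted the medians were 1.46 and 1.41. In keratinocyte-like cells antigen presentation genes were lower in 12 of 20 cases and higher in 1, with a median of -1.12, below all 10000 random lists, and of -1.14 with free RNA subtracted. Cluster 26 of this class, with 500 control and 12 IMQ cells, had the Langerhans cell marker Cd207 among its leading genes, and 21 of these control cells held 1252 Cd207 UMIs. Over the 1589 control and 2133 IMQ cells of the class without a Cd207 UMI the median was -0.20, with 5 of 19 genes lower and 3 higher, and without cluster 26 it was -0.22.

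The animals were described as female, yet transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted at 14276, 4618, 740 and 2210 UMIs in the control and 10491, 6284, 1087 and 1945 UMIs in the IMQ library, and Xist, the transcript of the inactive X chromosome, at 9 and 13 UMIs. Among kept cells with at least 20000 UMIs, 96.1% of control and 94.97% of IMQ cells had a Y-linked UMI, which argues against free RNA or a small number of male cells. Reads of X-linked copies in female cells are argued against by an Xist level of at most 0.0940 CPM. Of 13751 cells with an Xist or Y-linked UMI, 0% held Xist without a Y-linked UMI. Since 7 and 13 cells held Xist at all, this share could not have exceeded 0.145% and decides nothing. Y-linked UMIs in 96.1% and 94.97% of deep cells, with almost no Xist, argue against female animals as the source of either library. Male animals in both libraries remain the explanation that these values do not argue against. Both libraries showed this, so these transcripts do not set the 2 libraries apart.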
